A study of Homo sapiens with 8 samples.

How the data were processed

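RNA-seq was made from SW1990, an established cell line of pancreatic ductal adenocarcinoma. The sample titles place all 8 samples in the side population, the fraction of cells that exports a DNA-binding dye, and divide them into a control and a PAF1 CRISPR knockdown. Each group had 2 libraries, and each library was sequenced on 2 lanes. Per the labels' protocols, RNA was isolated with a mirVana kit, had an integrity number of 10 in all samples, and was made into libraries with a TruSeq RNA kit. The strand setting of the counting was not given in the sources used here, so overlapping and antisense genes could not be told apart.

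The deposited values were whole-number counts per gene and lane, with no normalization, in 1 table of 60483 genes and 8 count columns. Per the submitters' processing notes, FastQC, HISAT2 and featureCounts were used, and both hg19 and GRCh38 were named, without versions or roles. The coordinates in the table were compared with GENCODE release 29 on GRCh38. Of the 60483 identifiers, 56753 were in that annotation, and 56729 of these overlapped the annotated span. Coordinates are given on GRCh38. A gene symbol was found for 56321 identifiers. All 37 mitochondrial genes had a count of 0 in every column.

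The column names gave the group and lane but not the library number of the titles. In each group, the name of 1 library began with SP and the name of the other did not. Libraries are therefore called SP-prefixed or unprefixed. The titles give SP as short for side population in all samples, and why only some library names carry it was not stated. Whether the unprefixed libraries are side population cells could not be settled from the labels. The word CRISPR stood in 3 of the 4 library names and not in that of the unprefixed control.

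Lanes were compared by a chi-square test over genes and were summed within libraries, because the labels call them technical replicates. The comparison had 2 libraries per group. Nothing in the labels says that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Total counts ranged from 17234973 to 22348416 per library.

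Counts were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test, TMM normalization, the default expression filter with a minimum count of 10, and Benjamini-Hochberg adjustment at 0.05. The filter left 16417 genes. The test had no covariates and 2 residual degrees of freedom before moderation. CPM values were scaled by the TMM-normalised library sizes. Standard errors of log2 fold changes were derived from the F statistic. A second fit with a term for the column-name prefix, with 1 residual degree of freedom, was chosen after the data were seen. The planned block by library number could not be made, since the columns carry no such number.

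Of the fixed gene lists, 45 in all, 41 had at least 5 measured members and were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Fold changes against the genomic span of genes were described by Spearman's rho across genes, and genes were also summarised by chromosome and in windows of 25 neighbouring genes. No p-value was given for these, because genes are not independent replicates. Medians were set against 10000 random gene lists.

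Groups, tests, gene lists, other settings and the rule for named genes were set before the data were examined. The rule named the PAF1 complex, PHF5A and DDX3X in any case. It then took up to 15 genes per direction with the largest fold changes among genes past the threshold, with a mean of at least 5 CPM, a gene symbol and both libraries labelled PAF1 knockdown on the same side of both controls. Up to 4 members per list past the threshold were added, as were all measured members of the stemness, pluripotency and transporter lists. The planned fit passed no gene, so this rule named 0 genes by size there. The same rule was applied to the fit with the prefix term, a choice made after values were seen. Genes outside the rule are named only as members of a fixed list, or in the closing section. Markers of other cell types are given as CPM, without a list test.

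The alternatives were DESeq2 1.42.0, limma-voom, other scalings (RLE, upper quartile, library size), other filters, each lane alone, lanes as samples, protein-coding genes alone, robust and older variants of edgeR, and leaving out each library. Removal of a trend with GC content or exon length (loess span 0.5) and blocks by pairs of libraries were added after the data were seen. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.

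The gene tests were tested on simulated data with the libraries' own sizes. Before changes were added, all libraries had a common mean per gene for the planned fit. For the fit with the prefix term, the libraries of a pair had a common mean. The distance of the SP-prefixed control alone was not simulated. For the comparison of libraries labelled PAF1 knockdown with controls, the planned edgeR fit on 16148 genes recovered 60 of 100 genes changed 2-fold and 96 of 100 changed 4-fold. Of its 184 calls, 28 were false, a larger share than the threshold of 0.05. With the prefix term, on 16187 genes, 78 of 100 and 99 of 100 were recovered, and 16 of 193 calls were false. The simulated means and dispersions differed between the fits, so these values do not rank them. In a simulation of 40 lists of 20 genes over 16417 genes, camera recovered 5 of 5 lists shifted by 0.5 (log2) with 0 false calls, whereas an estimated correlation and fry each recovered 0 of 5. The simulated genes varied independently, so false calls for lists whose members move together were not measured. In the data the estimated correlation was -0.03 for mesenchymal genes, 0.70 for G1/S genes and 0.91 for ER stress and ATF4 targets. Counting intervals are 95% exact Poisson intervals and cover counting error only, since the reads carry no molecular identifiers.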

Results

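The transcriptome of SW1990 pancreatic cancer cells was sequenced to compare control cells with cells subjected to CRISPR knockdown of PAF1, a subunit of the RNA polymerase II associated PAF1 complex that acts in transcription elongation. The series title links PAF1 to stemness through PHF5A and DDX3, so the targeted gene, its partners and stemness genes were read first. There were 2 libraries per group, each on 2 lanes. The unprefixed and SP-prefixed controls held 22348416 and 20334075 counts, and the unprefixed and SP-prefixed libraries labelled PAF1 knockdown held 17234973 and 19157966. Between 24358 and 25475 genes had at least 1 count, and the 10 most abundant genes took 2.87% to 3.74% of the counts. Lanes of the same library differed by little more than sampling noise, with a chi-square per degree of freedom of 1.01 to 1.03, and were counted as 1 sample. The same measure between libraries was 10.1 for the libraries labelled PAF1 knockdown, 41.2 for the controls and 39.8 for the SP-prefixed pair. The controls therefore differed from each other about as much as that pair did. The unprefixed pair had 11.96, little more than the libraries labelled PAF1 knockdown. The SP-prefixed control against the unprefixed library labelled PAF1 knockdown gave 37.83, and the unprefixed control against the SP-prefixed library labelled PAF1 knockdown 27.75. Each other library thus differed most from the SP-prefixed control.

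PAF1 mRNA was highest in the unprefixed control, and the counting intervals of the other libraries overlapped. The unprefixed library labelled PAF1 knockdown was below the unprefixed control, whereas the SP-prefixed one was not below the SP-prefixed control. Libraries are paired here by the prefix alone, since the labels do not pair them. PAF1 (ENSG00000006712, chromosome 19, 39385852 to 39391195, minus strand, GRCh38) had 55.2 CPM (95% counting interval 52.2 to 58.4) in the unprefixed control and 43.9 CPM (41.1 to 46.9) in the SP-prefixed control. It had 41.7 CPM (38.8 to 44.9) in the unprefixed and 44.4 CPM (41.5 to 47.5) in the SP-prefixed library labelled PAF1 knockdown. The log2 fold change was -0.40 in the unprefixed pair and 0.02 in the SP-prefixed pair. Over both pairs it was -0.20 ± 0.16 (SE, n = 2 per group; edgeR, Benjamini-Hochberg adjusted p = 0.659), and with the prefix term -0.19 ± 0.16 (edgeR, adjusted p = 0.623). The mRNA level therefore did not separate the groups, and every direction given for libraries labelled PAF1 knockdown rests on their labels. Protein was not measured.

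The other subunits of the PAF1 complex and the partners named in the series title were close to their control levels. Log2 fold changes were 0.11 ± 0.12 for CDC73, 0.10 ± 0.14 for CTR9, 0.10 ± 0.17 for SKIC8, 0.06 ± 0.13 for LEO1 and 0.02 ± 0.12 for RTF1 (SE, n = 2 per group). PHF5A, a component of the SF3b splicing complex, had 41.8 and 37.0 CPM in the controls and 43.3 and 50.1 CPM in the libraries labelled PAF1 knockdown, unprefixed first. Its log2 fold change was 0.24 ± 0.15 (edgeR, Benjamini-Hochberg adjusted p = 0.568). DDX3X, an RNA helicase, had 417 and 392 CPM in the controls against 436 and 447 CPM, a log2 fold change of 0.13 ± 0.12 (edgeR, adjusted p = 0.732). None of the 6 measured subunits passed the test, over all genes or adjusted over the list alone, and the camera adjusted p of the complex was 0.621.

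THBS1, a matricellular glycoprotein, had 242 and 232 CPM in the controls and 512 and 733 CPM in the libraries labelled PAF1 knockdown. CEACAM5, a cell-surface glycoprotein used as a carcinoma marker, had 44.2 and 18.1 CPM against 9.78 and 3.58 CPM. No gene passed the planned edgeR test of 16417 genes after Benjamini-Hochberg adjustment (lowest adjusted p = 0.175, shared by THBS1, whose log2 fold change was 1.40 ± 0.19). At an unadjusted p under 0.05, 1841 genes stood out. DESeq2 passed 236 genes (64 higher, 172 lower) and limma-voom 0. With the prefix term, which removes the difference between the pairs, edgeR passed 320 genes (89 higher, 231 lower), of which 220 changed at least 2-fold. Of the 320, 318 had the same sign in both pairs, against 62.3% of all 16417 genes. That fit selects genes on which the pairs agree, so the shared sign is not separate evidence. DESeq2 without the prefix term passed 214 of these 320. Both libraries labelled PAF1 knockdown lay on one side of both controls for 7321 genes, or 44.6%. The possible splits of the libraries into pairs average 33.3%, and genes move together, so this share is not a test of the groups. The count without the prefix term depended on 2 libraries, being 1316 without the unprefixed control and 208 without the SP-prefixed control.

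**Figure D1:**
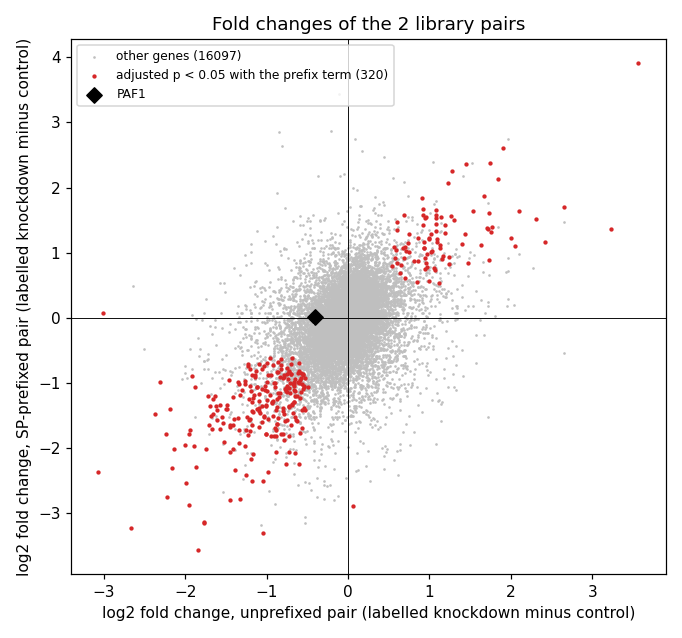
Log2 fold change of the library labelled PAF1 knockdown over the control for 16417 genes, in the unprefixed pair (x axis) and in the SP-prefixed pair (y axis). Red points are the 320 genes past the edgeR threshold with the prefix term, grey points are the other genes, and the diamond marks PAF1 at -0.40 and 0.02.

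The 15 named genes that rose in the fit with the prefix term had log2 fold changes from 1.34 (LYPD1) to 2.33 (IGFN1). DIO2, the deiodinase that activates thyroid hormone, rose by 2.08 ± 0.20 (SE, n = 2 per group; edgeR, Benjamini-Hochberg adjusted p = 0.00538), from 7.23 and 10.8 CPM to 24.4 and 56.4 CPM. IL7R, a cytokine receptor subunit, rose by 2.22 ± 0.37, from 1.23 and 3.84 CPM to 12.4 and 10.1 CPM. FST, a secreted activin antagonist, rose by 1.78 ± 0.30, and the adhesion molecule MCAM by 1.87 ± 0.25. DPYSL3, a cytoskeletal phosphoprotein, rose by 1.41 ± 0.16 (edgeR, adjusted p = 0.00783), from 15.4 and 14.9 CPM to 38.3 and 42.6 CPM. THBS1 rose by 1.37 ± 0.16 (edgeR, adjusted p = 0.00783). PTX3, a soluble pattern recognition molecule, rose by 1.38 ± 0.16, RGS4, a regulator of G protein signalling, by 1.36 ± 0.15, and BMPER, a secreted regulator of BMP signalling, by 1.35 ± 0.20. LZTS1 (1.57), ENOX1 (1.56), RAB3B (1.52) and the zinc finger gene BNC2 (1.38) completed the group.

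The 15 named genes that fell in the same fit had log2 fold changes from -1.53 (WFDC2 and BICDL2) to -2.49 (KRT16). CEACAM5 fell by 2.25 ± 0.18 (SE, n = 2 per group; edgeR, Benjamini-Hochberg adjusted p = 0.0044), the smallest adjusted p of the fit. The keratin gene KRT16 fell by 2.49 ± 0.32, from 8.33 and 12.96 CPM to 2.37 and 1.37 CPM. Both KRT16 and CEACAM5 have close paralogs that can share reads. KLK11, a secreted serine protease, fell by 1.88 ± 0.18 from 36.8 and 22.2 CPM to 9.44 and 6.38 CPM. CHST6 and CHST4, which are sulfotransferases, fell by 2.12 ± 0.29 and 1.61 ± 0.18. WFDC2, a secreted whey acidic protein family member, fell by 1.53 ± 0.17 from 50.02 and 38.9 CPM to 19.7 and 11.7 CPM. GRB7, an adaptor of receptor tyrosine kinases, fell by 1.67 ± 0.23, and NGFR, a neurotrophin receptor, by 1.72 ± 0.21. LYPD2 (-1.87), CLIC5 (-1.84), PRR36 (-1.82), SLC44A4 (-1.75), SPNS2 (-1.64) and ATP6V1FNB (-1.57) were the other members of this group.

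Genes of the mesenchymal list were higher and genes of the epithelial list lower in the libraries labelled PAF1 knockdown. Of 16 measured mesenchymal genes, 13 had a positive log2 fold change and the median was 0.52, with 0.57 in the unprefixed pair and 0.56 in the SP-prefixed pair. VIM, the intermediate filament vimentin, had 161 and 199 CPM in the controls and 317 and 393 CPM in the libraries labelled PAF1 knockdown, and CDH2 (N-cadherin) 2.47 and 2.44 CPM against 6.08 and 7.38 CPM. The planned edgeR fit passed 7 members adjusted over the list alone (VIM, CDH2, SNAI2, ZEB1, SPARC, SNAI1 and ZEB2, all higher) and 0 over all genes. With the prefix term VIM rose by 0.97 ± 0.13 (SE, n = 2 per group; edgeR, Benjamini-Hochberg adjusted p = 0.0105) and CDH2 by 1.45 ± 0.24 (edgeR, adjusted p = 0.0193), and adjusted over the list alone 11 members rose and 1, MMP14, fell. Of 18 epithelial genes, 15 had a negative log2 fold change, with a median of -0.32 (-0.26 and -0.34 in the pairs). In both fits 5 of them, the claudins CLDN3, CLDN4 and CLDN7, the tight junction gene OCLN and RAB25, fell adjusted over the list alone, and 0 passed over all genes. CDH1, which encodes E-cadherin, had a log2 fold change of -0.23 ± 0.14 and EPCAM of -0.15 ± 0.12. The camera test passed both lists (adjusted p = 1.1e-05 for mesenchymal and 0.000282 for epithelial genes). With an estimated correlation, which recovered 0 of 5 shifted lists in the simulation, the camera adjusted p was 0.903 for each. Fry gave an adjusted p of 0.0894 for each list. Its test for change in either direction gave 0.00194 for each in the planned fit. With the prefix term that fry test gave 0.217 for mesenchymal and 0.101 for epithelial genes.

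Mucin genes were lower as a list, with members that moved differently between the pairs. Of 9 measured mucins, 8 had a negative log2 fold change and the median was -0.998, with -0.34 in the unprefixed and -1.22 in the SP-prefixed pair (camera adjusted p = 0.024, and 0.903 with an estimated correlation). MUC1, a transmembrane mucin, had 229 and 143 CPM in the controls and 115 and 71.5 CPM in the libraries labelled PAF1 knockdown. With the prefix term MUC1 fell by 0.997 ± 0.13, the gel-forming MUC5B by 1.41 ± 0.21 and MUC20 by 1.15 ± 0.17 (SE, n = 2 per group; edgeR, Benjamini-Hochberg adjusted p = 0.0105, 0.0135 and 0.0135), and adjusted over the list alone 6 members fell and 1, MUC6, rose. The planned fit passed 4 members adjusted over the list alone and 0 over all genes. The SP-prefixed control held far more MUC16 (804 CPM) and MUC4 (196 CPM) than the unprefixed control (103 and 27.9 CPM). Without that library the camera adjusted p of the mucins was 0.773, and without the unprefixed library labelled PAF1 knockdown it was 0.107.

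**Figure D2:**
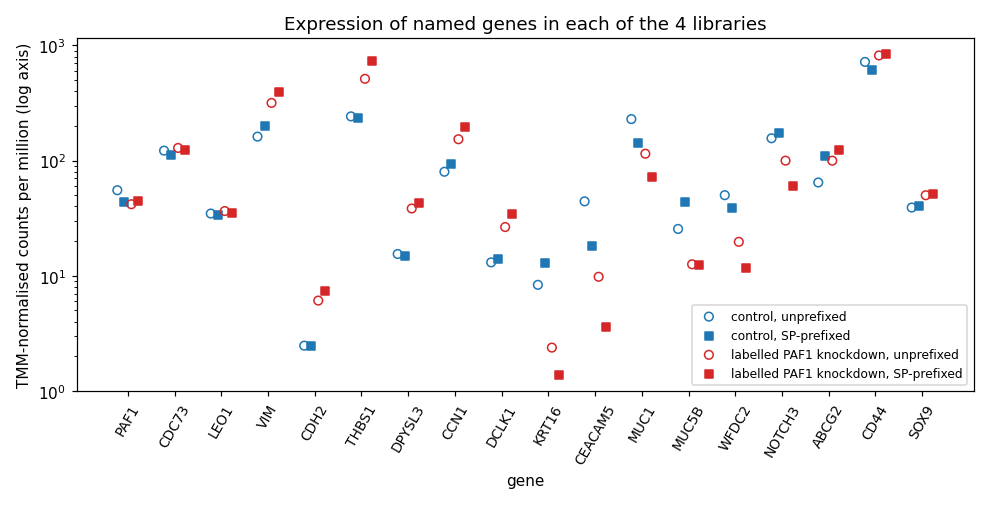
TMM-normalised CPM (log axis) of 18 genes in the 4 libraries, 1 point per library, for controls and libraries labelled PAF1 knockdown with and without the SP prefix. Both libraries labelled PAF1 knockdown lie above both controls for VIM, CDH2, THBS1 and DPYSL3 and below both for CEACAM5, MUC1 and WFDC2, whereas for PAF1 they do not separate from the controls.

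The stemness lists had no shared direction. Of 16 measured pancreatic cancer stem cell markers, 11 had a positive log2 fold change and the median was 0.17 (camera adjusted p = 0.124). DCLK1, a microtubule-associated kinase used as a tuft cell and stem cell marker, had 13.1 and 14.01 CPM in the controls and 26.5 and 34.4 CPM in the libraries labelled PAF1 knockdown. It rose by 1.16 ± 0.17 with the prefix term (SE, n = 2 per group; edgeR, Benjamini-Hochberg adjusted p = 0.0135) and was the member of this list that passed over all genes. The list had 2 members past the planned test adjusted over the list alone, and 3 with the prefix term (2 higher, 1 lower). CD44, SOX9, NES and BMI1 had log2 fold changes of 0.32 ± 0.14, 0.35 ± 0.13, 0.72 ± 0.17 and 0.37 ± 0.17, and CD9, CD24, EPCAM and ALDH1A3 of -0.55 ± 0.15, -0.57 ± 0.42, -0.15 ± 0.12 and -0.12 ± 0.13. The values were 0.00 ± 0.18 for MET, 0.03 ± 0.12 for CTNNB1, 0.02 ± 0.22 for TSPAN8, 0.40 ± 0.28 for LRIG1, 0.78 ± 0.45 for KIT and -0.28 ± 0.14 for MSI2. PROM1 and ALDH1A1 had at most 2 counts in any library.

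Of the pluripotency factors, 6 were measured, with a median log2 fold change of -0.56 (camera adjusted p = 0.111). Of these, 5 had a negative log2 fold change, and the median was -0.066 in the unprefixed and -0.785 in the SP-prefixed pair. KLF5 had 345 and 495 CPM in the controls against 263 and 253 CPM in the libraries labelled PAF1 knockdown, a log2 fold change of -0.70 ± 0.18 (SE, n = 2 per group; edgeR, Benjamini-Hochberg adjusted p = 0.263). It was the 1 member past the test adjusted over the list alone. KLF4 (-0.65 ± 0.34), MYC (-0.11 ± 0.20), SALL4 (-0.71 ± 0.37), SOX2 (-0.47 ± 0.36) and POU5F1 (0.05 ± 0.33) did not pass, and SOX2 and POU5F1 stood at no more than 1.91 CPM. NANOG, LIN28A, LIN28B and PRDM14 had 0 counts in all 4 libraries, so no difference was detectable at this depth. Of 11 measured ABC efflux transporters, ABCC4 rose by 0.75 ± 0.16 and ABCA3 fell by 1.29 ± 0.22 with the prefix term (edgeR, adjusted p = 0.0467 and 0.0234), and the list did not pass (camera adjusted p = 0.232). A negative log2 fold change was found for 9 of the 11, and the median was -0.043 in the unprefixed and -0.632 in the SP-prefixed pair. In the planned fit 3 members passed adjusted over the list alone and 0 over all genes. ABCG2, the transporter that exports the dye in many side populations, had 64.5 and 108 CPM in the controls and 99.7 and 124 CPM in the libraries labelled PAF1 knockdown, a log2 fold change of 0.37 ± 0.25 (edgeR, adjusted p = 0.602). Log2 fold changes were -0.57 ± 0.15 for ABCA2, -0.05 ± 0.21 for ABCA5, -0.42 ± 0.23 for ABCC1, -0.38 ± 0.56 for ABCC2, -0.45 ± 0.22 for ABCC3, -0.24 ± 0.12 for ABCC5, -0.93 ± 0.43 for ABCC6 and 0.00 ± 0.13 for ABCC10.

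Genes of DNA replication, mitosis, DNA repair and protein folding were slightly higher as lists in the libraries labelled PAF1 knockdown, and replication-dependent histone genes were lower. The median log2 fold change was 0.21 over 26 G1/S genes, 0.16 over 28 G2/M genes, 0.13 over 25 DNA repair genes, 0.32 over 15 heat shock genes and -0.49 over 12 histone genes (camera adjusted p = 0.00485, 0.0059, 0.0189, 0.00396 and 0.0102, and 0.903 for each with an estimated correlation). The planned fit passed 0 members of these 5 lists, over all genes or adjusted over the list alone, while 1841 genes had an unadjusted p under 0.05. With the prefix term 6 heat shock genes, among them HSPA8 (0.88 ± 0.24), HSPH1 (0.62 ± 0.17) and HSP90AA1 (0.52 ± 0.15), rose adjusted over the list alone and 0 over all genes. HSPA8, a constitutive chaperone, had 557 CPM in the SP-prefixed control and 1536 to 1820 CPM in the other libraries. The histone gene H2BC21 fell by 1.21 ± 0.21 (SE, n = 2 per group; edgeR, Benjamini-Hochberg adjusted p = 0.0253), and 4 of the histone genes, which share reads with close copies, fell adjusted over the list alone. The G1/S median was -0.05 in the unprefixed pair and 0.49 in the SP-prefixed pair. Without the SP-prefixed control the camera adjusted p was 0.793 for G1/S, 0.298 for DNA repair and 0.0709 for heat shock genes. Without the unprefixed control it was 0.267 for G2/M and 0.289 for histone genes, and without the SP-prefixed library labelled PAF1 knockdown 0.235 for G2/M, 0.225 for histone and 0.183 for DNA repair genes.

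Targets of the YAP/TEAD transcription factors were higher, with a median log2 fold change of 0.33 over 16 genes (0.38 and 0.14 in the pairs; camera adjusted p = 0.0109, and 0.903 with an estimated correlation). CCN1, a matricellular protein, had 79.9 and 92.5 CPM in the controls and 153 and 194 CPM in the libraries labelled PAF1 knockdown. It rose by 1.01 ± 0.14 with the prefix term (SE, n = 2 per group; edgeR, Benjamini-Hochberg adjusted p = 0.0105). Adjusted over the list alone, 8 members including ANKRD1, AXL and CCN2 rose with the prefix term and 1, CCN1, in the planned fit. Without the unprefixed control the camera adjusted p was 0.295. In other lists, which did not pass as lists, NOTCH3 fell by 1.09 ± 0.20, FOS by 1.48 ± 0.25, PLAT by 1.27 ± 0.23, MMP15 by 0.72 ± 0.15 and SCD by 1.37 ± 0.27, while DKK1 rose by 0.80 ± 0.13, CA2 by 1.21 ± 0.16 and CXCL1 by 1.06 ± 0.16 (edgeR with the prefix term, adjusted p of 0.0105 to 0.0454). The fall of SCD rested largely on the SP-prefixed control, which had 785 CPM against 141 to 222 CPM in the other libraries. Its log2 fold change was -0.65 in the unprefixed and -2.08 in the SP-prefixed pair. SCD did not pass DESeq2 (adjusted p = 0.607 without and 0.553 with the prefix term). The camera adjusted p was 0.652 for the Notch pathway, 0.309 for Wnt/beta-catenin targets, 0.961 for the Hedgehog pathway, 0.241 for TGF-beta targets, 0.101 for immediate early genes and 0.516 for ribosomal proteins.

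**Figure D3:**
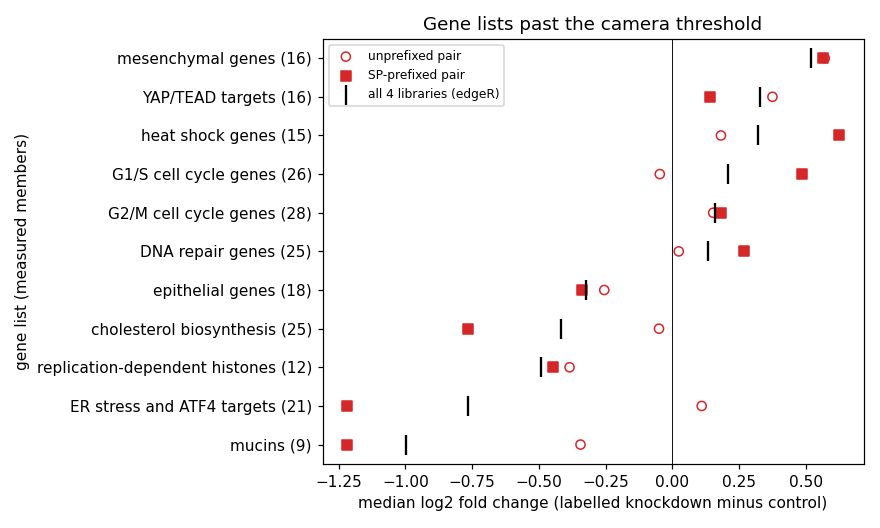
Median log2 fold change over the measured members of 11 gene lists in the unprefixed pair, in the SP-prefixed pair and in the planned edgeR fit. The mesenchymal medians of the pairs lie close together at 0.57 and 0.56, whereas those of ER stress and ATF4 targets lie at 0.11 and -1.22.

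Sterol synthesis and amino acid stress genes differed between the pairs. The median log2 fold change of 25 cholesterol biosynthesis genes was -0.05 in the unprefixed and -0.77 in the SP-prefixed pair, and that of 21 ER stress and ATF4 targets 0.11 and -1.22. ASNS, which makes asparagine and is a target of ATF4, had 17.4 CPM in the unprefixed and 257 CPM in the SP-prefixed control, against 21.1 and 45.3 CPM in the libraries labelled PAF1 knockdown. INSIG1, a regulator of sterol synthesis, had 20.1 and 118 CPM against 19.4 and 47.4 CPM. Neither list passed the planned test (camera adjusted p = 0.0793 and 0.162), and both passed with the prefix term (camera adjusted p = 0.00174 and 0.018, and 0.90 with an estimated correlation). With that term TM7SF2, a sterol reductase, fell by 0.91 ± 0.16 and CTH, an enzyme of cysteine synthesis, by 1.56 ± 0.32 (SE, n = 2 per group; edgeR, Benjamini-Hochberg adjusted p = 0.0256 and 0.0432). Adjusted over the list alone 5 sterol and 6 ATF4 genes fell with the prefix term and 0 in the planned fit. Without the SP-prefixed control both lists turned upward, with a camera adjusted p of 0.279 for cholesterol genes and 0.036 for ATF4 targets.

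Markers of other cell types were mostly absent or at similar levels in the 4 libraries. The summed CPM of 14 fibroblast markers was 130 and 140 in the controls and 121 and 121 in the libraries labelled PAF1 knockdown. COL1A1 stood at 29.8 to 37.9 CPM, and COL1A2, COL3A1 and DCN at no more than 0.053 CPM. Among fibroblast markers COL6A3 rose by 1.03 ± 0.17 with the prefix term (SE, n = 2 per group; edgeR, Benjamini-Hochberg adjusted p = 0.021). The summed CPM of endocrine markers was 49.5 and 64.5 in the controls and 83.3 and 82.7 in the libraries labelled PAF1 knockdown, mostly from SCG2, which rose by 0.90 ± 0.15 (edgeR with the prefix term, adjusted p = 0.019). INS was at no more than 0.044 CPM and GCG had none. Sums were 11.8 and 12.8 against 7.70 and 7.69 CPM for acinar markers, 73.4 and 71.6 against 77.7 and 61.6 CPM for leukocyte markers, and 69.9 and 81.4 against 71.1 and 86.5 CPM for endothelial markers. Erythroid markers reached at most 0.17 CPM in sum. PTPRC, which all leukocytes express, was at no more than 0.116 CPM.

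Because PAF1 acts in elongation, fold changes were set against the genomic span of 16417 genes. Spearman's rho across genes was -0.02 over both pairs, 0.08 in the unprefixed and -0.08 in the SP-prefixed pair. The same measure between the 2 controls was 0.10, so the pairs differed no more with gene span than did the controls. The 470 genes between PAF1 and the end of the long arm of chromosome 19 were also compared with other genes, since a CRISPR break can remove the distal part of a chromosome. Their median log2 fold change was -0.09 (interquartile range -0.36 to 0.10), with -0.08 in each pair. The 623 genes on the other side of PAF1 on chromosome 19 had a median of -0.07, genes on chromosome 14 of -0.09 and all genes of -0.01. The telomeric median lay at percentile 0.02 of 10000 random lists of 470 genes. Those lists were matched on mean expression but not on position or GC content, and fold changes fell with GC content (Spearman's rho -0.15). The percentile therefore cannot tell a loss beyond PAF1 from such trends. In windows of 25 neighbouring genes, 2 overlapping windows of 3179, both on chromosome 16 (2737076 to 3060726 and 2830169 to 3142805), had a median beyond 0.5 in either pair, at -0.35 and -0.54.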

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

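The tests of the SP-prefixed control against GC content, abundant genes and a shared state were chosen only after its values were seen. The median log2 fold change had opposite signs in the pairs in 16 of 43 lists, and in 5 of these both medians were at least 0.1 in size, a limit set after the data were seen. The difference between the pairs was not tested. In the SP-prefixed and unprefixed pair the medians of these 5 were -1.218 and 0.11 for ER stress and ATF4 targets, -0.846 and 0.145 for immediate early genes, and -0.819 and 0.219 for NRF2 targets. They were -0.73 and 0.276 for NF-kB targets and cytokines, and -0.132 and 0.129 for ductal genes and keratins.

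The SP-prefixed control stood above the mean of the other libraries in 63 of 65 ATF4, NRF2 and sterol genes, by a median log2 difference of 1.097 (SD over genes 0.881), among them ASNS, TRIB3 (247 CPM against 19.3 to 41.4), AKR1C1 (136 CPM against 14.3 to 55.4) and INSIG1 (118 CPM against 19.4 to 47.4). A trend with GC content is argued against by a median of 1.069 with that trend removed, and a few dominant genes by the 10 most abundant, whose share was 0.799 of the smallest share in any other library. A state shared by both SP-prefixed libraries may contribute: in the SP-prefixed minus the unprefixed library labelled PAF1 knockdown, the list medians were 0.17 for ATF4, 0.21 for NRF2 and 0.45 for sterol genes, at percentile 99.92 or higher of random lists. In that comparison 13 of 21 ATF4, 18 of 20 NRF2 and 25 of 25 sterol members were higher. The random lists were matched on mean expression only, whereas members of these lists move together. Their estimated correlation in the planned fit was 0.91 for ATF4, 0.98 for NRF2 and 0.76 for sterol genes. A high percentile between 2 single libraries can therefore arise without a state tied to the prefix. Mucins, which had the largest excess of any list in the SP-prefixed control (1.44), were divided in the same comparison. Their median was -0.02 (percentile 38.93), with 4 of 9 members higher. MUC16 was higher by 1.81, MUC4 by 1.28, MUC2 by 1.20 and MUC5AC by 0.90, so the median does not decide for mucins. What sets the SP-prefixed control further apart stays open. Whether culture, sorting or the knockdown itself plays a part was not tested. The titles use SP for the side population in all samples, so the labels do not say what the prefix separates.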

How the results depend on the processing

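The blocks by pairs of libraries, the GC and exon length corrections and all settings of the fit with the prefix term were chosen after the data were seen. No paired analysis by library number was possible because the count columns carry no number. The replicate block by column-name prefix took the planned count of 0 genes to 320 and that of lists from 9 to 11, adding cholesterol and ATF4 genes (camera adjusted p = 0.00174 and 0.018), and changed no other list call. A block by crossed pairs gave 0 genes in edgeR (1374 at an unadjusted p under 0.05). Fold changes of the pairs correlated at 0.408 across genes, and those of the crossed pairs at 0.139. The planned count was 236 with DESeq2, 2234 with lanes as samples, and 0 to 1316 when each library was left out, where the lone library is assumed to vary like the others. It was 0 under the other settings of edgeR and with limma-voom (1841 and 1800 genes at an unadjusted p under 0.05 in the planned edgeR fit and limma-voom). With the prefix term it was 618 with upper-quartile scaling, 4283 with lanes as samples, 673 with lane 2 alone, 586 with protein-coding genes alone and 0 without a filter on low counts (2606 at an unadjusted p under 0.05 of 30366 genes, and 215 with DESeq2), and otherwise 215 to 428. Lanes as samples treat technical repeats as replicates, which by construction lowers the spread; for the other settings the cause was not tested. Leaving out a library from this fit left no residual degrees of freedom. With the GC trend removed it passed 163 higher and 265 lower genes, and 309 of the 320 genes were kept. The lists past the threshold numbered 8 to 16 when each library was left out, 0 with an estimated correlation, 0 with fry and 3 with its test for change in either direction. Leaving out each library gave adjusted p from 6.25e-08 to 0.463 for ATF4 and from 2.19e-06 to 0.827 for cholesterol genes, both turning upward without the SP-prefixed control (0.036 and 0.279). Mesenchymal and epithelial lists passed with each library left out (adjusted p up to 0.000731 and 0.00837). The log2 fold change of PAF1 stayed below 0 and short of the threshold throughout, from -0.357 to -0.014. The median of genes telomeric of PAF1 was -0.1 without a filter, -0.074 at 1 CPM, -0.08 with RLE factors and -0.107 to -0.059 when each library was left out; the cause was not tested. Of 1838 values of named genes in other settings of the planned fit, 245 moved past the threshold and 34 changed sign. Of 1310 with the prefix term, 71 lost the threshold, 29 gained it and 16 changed sign. The median shift of all genes stayed between -0.019 and -0.006 under every scaling. At this depth genes under about 1 CPM rest on few counts.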

Other observations

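The comparison by prefix, the medians of long transcripts and the tests of explanations for PAF1 and for mesenchymal and epithelial genes were chosen only after the data were seen. Taking group into account, 41 genes differed between SP-prefixed and unprefixed libraries (25 higher and 16 lower in the SP-prefixed; edgeR, Benjamini-Hochberg). Among those higher were MUC16 by 2.39 ± 0.24, MUC4 by 2.05 ± 0.29, MUC2 by 2.01 ± 0.31 and MUC5AC by 1.34 ± 0.19 (log2, SE), the serine synthesis enzyme PHGDH by 1.59 ± 0.24, and INHBE, a secreted activin subunit, by 3.47 ± 0.33. KRT6C (-2.82 ± 0.31), IVL (-1.72 ± 0.25), SPRR3 (-1.58 ± 0.24) and KRT13 (-0.91 ± 0.14), which encode proteins of stratified squamous epithelium, were lower. These genes were named after their values were seen. Each of them differed more between the controls than between the libraries labelled PAF1 knockdown. The 2 differences were 4.24 and 1.29 for INHBE, -3.79 and -0.71 for KRT6C, 2.97 and 1.81 for MUC16, and -0.98 and -0.83 for KRT13. The averages therefore do not hold equally for both SP-prefixed libraries. Of the fixed lists, cholesterol genes had a median of 0.75 (camera adjusted p = 3.9e-14), NRF2 targets of 0.75 (1.1e-09), ATF4 targets of 0.88 (3.4e-08) and histone genes of -0.52 (1.2e-05), each with an adjusted p of 0.929 with an estimated correlation. Between the libraries labelled PAF1 knockdown alone, the medians of these lists were 0.45, 0.21, 0.17 and -0.42.

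DYNC1H1, UBR4, HUWE1, SYNE2 and AHNAK, which have very long transcripts, were also higher in the SP-prefixed libraries, by 0.94, 1.00, 0.85, 1.00 and 0.78 (log2). Over 316 protein-coding genes with at least 15 kb of exon, the median of SP-prefixed minus unprefixed was 0.18 in the controls (interquartile range -0.02 to 0.48) and 0.04 in the libraries labelled PAF1 knockdown (-0.09 to 0.22). Over the other 12599 protein-coding genes the medians were -0.02 and 0.

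There are 3 splits of the 4 libraries into pairs, too few for a share under 0.05. At an unadjusted p under 0.05 without a prefix term, the group labels gave 1841 genes and the highest other split, by prefix, gave 868.

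PAF1 mRNA was lower in the unprefixed library labelled PAF1 knockdown (-0.40) but not in the SP-prefixed one (0.02). Labels exchanged within the SP-prefixed pair would not account for this, since its libraries had 43.9 and 44.4 CPM of PAF1 and would differ as little after an exchange. Across genes the fold changes of the pairs correlated at 0.408. An exchange predicts a value below 0 only if the pairs share a knockdown effect, which PAF1 mRNA did not show. The gap between the pairs was at least 0.419 under 4 scalings, so the choice among them does not account for it. The TMM factors were close together (0.988 to 1.017), so this test had little room to move the gap. A GC trend does not account for the whole gap, which was 0.386 with the trend removed. The fold changes were then -0.291 and 0.095, so a part of the fall in the unprefixed pair cannot be told apart from a GC trend. The SP-prefixed control itself had less PAF1 mRNA than the unprefixed control (log2 difference -0.33). An edit that leaves the mRNA in place may underlie the pattern, but this was not tested, as protein and reads were not analysed here.

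Mesenchymal genes were higher and epithelial genes lower in both pairs. Fibroblast RNA is argued against by COL1A2, COL3A1 and DCN, which reached at most 0.053 CPM in the libraries labelled PAF1 knockdown. A GC trend is argued against for mesenchymal genes, whose median kept 108.9% of its size with the trend removed. For epithelial genes it kept 70.9% (-0.32 to -0.23, camera adjusted p = 0.00137), so a part of that shift cannot be told apart from a GC trend. With the trend kept, camera with an estimated correlation gave an adjusted p of 0.903 for either list. A response to the knockdown is a hypothesis that stays open for mesenchymal genes, as PAF1 mRNA did not separate the groups.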
